A study of Homo sapiens with 12 samples.

How the data were processed

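The data are 12 expression arrays of RNA from L428 and L1236, established cell lines of classical Hodgkin lymphoma. Each line was measured without treatment and after 1 µM 5-Aza-dC for 24 h followed by 72 h in drug-free medium, with 3 arrays per group. Groups were taken from the sample descriptions. The source name of 1 untreated L1236 array (replicate 1) describes treated L428 cells, so its labels conflict. Its description and its place in the series of titles put it in the untreated L1236 group, and its values correlated best with those of untreated L1236 replicate 3. The source name of treated L428 replicate 1 reads Aza, where the other treated arrays read 5-Aza-dC, and its description reads 5-Aza-dC. Nothing in the labels says that replicates were separate cultures, so the p-values measure only the spread between these samples.

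The deposited values are log2 signals, 1 per probe set and array, made with robust multichip averaging (RMA) per the submitters' processing notes and the design text. The version of RMA was not given in the sources used here. No scanner output and no detection calls were used here. The table covers 54675 probe sets, of which 62 are controls. The medians were 3.03, 3.09 and 3.02 in untreated L428, 3.01, 3.04 and 3.06 in treated L428, 3.02, 3.01 and 3.03 in untreated L1236, and 3.05, 3.03 and 3.04 in treated L1236. The log2 scale was read from the range of the values and the RMA step. How the submitters scaled or centred the arrays beyond RMA is unknown, and single-channel signals have no direction that could be turned. The design text names a whole-transcript array, while the probe set identifiers are those of a 3' expression array. The identifiers of the table were used, and this conflict stays open. Values of 2 to 3 lie at the lower end of the scale, so a fold change from such a level depends on where the submitters' processing placed that floor. Whether plain RMA gives so many values at that floor, and whether all 12 arrays were normalized together, could not be settled from the labels, so folds from the floor are uncertain in size.

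Gene names came from the platform annotation supplied with the table, which gave 41097 probe sets 1 gene symbol, 1801 several and 11777 none. Of the single-gene probe sets, 41043 were matched through their Entrez identifier to the RefSeq gene table of GRCh38.p14, which was used for names only. For a gene with several probe sets, the probe set with the highest mean over all 12 arrays was taken, which left 19775 genes. No dim gene was removed. Genes of near-identical families, such as the MAGEA, SSX and histone genes, share probe sequence, and their values are uncertain as to the family member.

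Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with 4 group means was fitted to all 12 arrays, followed by empirical Bayes moderation and Benjamini-Hochberg adjustment over the 19775 genes. A gene was called at an adjusted p under 0.05, and all tests were two-sided. The contrasts were treated minus untreated in each line, the L1236 response minus the L428 response, the mean of both responses, and untreated L1236 minus untreated L428. Counts of calls with at least a 2-fold change are given beside the total counts. The groups, tests, gene lists and alternative settings were fixed before the data were examined.

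A total of 23 gene lists were fixed in the same way. They hold cancer-testis antigens, germline and meiosis genes, interferon-stimulated genes, NF-kappaB targets, JAK-STAT pathway and target genes, MAPK and AP-1 response genes, B-cell programme genes and plasma-cell genes. They also hold Hodgkin Reed-Sternberg cell markers, MHC class I and class II presentation genes, p53 targets, pro-death and pro-survival apoptosis genes, cell-cycle and replication genes and CDK inhibitors. The rest are imprinted genes, genes of DNA methylation and decitabine metabolism, endogenous retroviral envelope genes, housekeeping genes, and markers of T and NK cells, of myeloid cells and of stromal, endothelial and epithelial cells. For 3 symbols in the lists the current name was entered by hand. Each list was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 23 lists of a contrast. Beside it, camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were run. Member counts are given after adjustment over all genes, and as adjusted over the list alone.

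The genes named were chosen by rule. In each line these were the 10 largest rises and 5 largest falls among called genes whose treated arrays all lay beyond all untreated arrays, a separation that chance gives in 10% of such comparisons. For the difference between the lines and for the untreated lines, the rule took the 5 largest called values in each direction, and for the mean response the 5 largest among genes called the same way in both lines. From each list it took up to 3 called members with the smallest adjusted p, or up to 2 members with the smallest p where none was called. DNMT1, DNMT3A, DNMT3B, TNFRSF8, CDKN1A, MYC and BCL2 were always included. Members at the end of these rankings were left out for length, and 1 gene that the rule selected is not reported here. Genes outside the rule are said to have been chosen after their values were seen.

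The alternatives were all probe sets, the lowest of 3 brightness classes removed, median centring, cyclic loess, array weights, a trended and robust prior, fits on only the groups compared, the replicate number as a block, and each array left out in turn. Leaving out all 4 arrays numbered 1, and a block spanning both lines, were added after the data were seen. Deviations from the group means correlated across genes at 0.250, 0.169 and 0.164 between same-numbered arrays of L428, and at up to 0.173 between differently numbered ones. Between the lines they did so at 0.360, 0.203 and 0.107 without treatment (others up to 0.275) and at 0.400, 0.313 and 0.243 with it (others up to 0.303). In L1236 the values were 0.05, -0.02 and 0.06 (others up to 0.0571). The highest of the others exceeded the lowest same-numbered value each time, so that a pairing of the arrays is uncertain. The replicate numbers came from the sample titles.

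The fit was tested on simulated data. Each array was drawn from the untreated mean of its line and 1 pooled spread per gene, equal in all groups. In the treated arrays 200 genes were changed, and the genes of the interferon-stimulated list were raised 2-fold. A spread that differs between groups was thus not simulated. The recovered numbers count only the 200 genes. For L428, 28 of 50 genes changed 2-fold, 43 of 50 changed 4-fold, 49 of 50 changed 8-fold and 49 of 50 changed 16-fold were recovered, with 13 false calls among 186. For L1236 the recovered numbers were 29, 42, 47 and 48 of 50, with 11 false calls among 180. For the mean response they were 37, 48, 49 and 50 of 50, with 14 false calls among 208. In simulated L428 lists, camera called 1 of 23 lists, the one that had been shifted. The simulated genes were drawn independently of each other. In the real lists the estimated correlation between genes had a median of 0.13 and reached 0.71. The simulation therefore cannot show how often camera calls lists of correlated genes falsely. Counts were also made for other splits of the arrays into groups, with 100 splits drawn where more existed. For the difference between the lines these were repeated with each gene's mean response subtracted from the treated arrays, which was added after the data were seen. Confidence intervals for slopes and medians came from 2000 bootstrap resamples of genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.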

Results

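Transcript levels were measured on 12 arrays of L428 and L1236 cells, lines of classical Hodgkin lymphoma, a tumour of B-cell origin whose cells have lost most of the B-cell programme. Each line was sampled untreated and after 5-Aza-dC, with 3 arrays per group. 5-Aza-dC (decitabine) is a cytidine analogue that enters DNA and traps DNA methyltransferases, so that methylation is lost as cells divide. Cells had received 1 µM for 24 h and had then grown for 72 h without it. The title of the series places the interest in the survival pathways that the drug activates, and the comparisons ask which genes changed in each line and where the lines differed. Levels are log2 signals, given as mean ± SD with n = 3, and changes are log2 differences ± SE from limma with adjusted p-values.

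Across genes, arrays of the same group correlated at 0.982 to 0.997, arrays of one line under different treatment at 0.962 to 0.987, and arrays of different lines at 0.911 to 0.937. Genes are not independent replicates. Treated replicate 1 of each line stood apart from the other treated arrays. The SD of its deviations from the group mean was 0.449 in L428 and 0.384 in L1236, against 0.156 to 0.315 in the other 10 arrays. Treated L428 replicate 1 correlated best with an untreated L428 array.

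In L428, IFI27, which encodes an interferon-induced mitochondrial protein, went from 2.41 ± 0.05 to 12.48 ± 2.22, a rise of 10.07 ± 1.01 (adjusted p = 9.54e-04). The antiviral genes TRIM22, CMPK2 and RSAD2 rose by 9.25 ± 0.74 (3.00e-04), 8.24 ± 0.66 (3.04e-04) and 8.21 ± 1.14 (0.00519), with adjusted p-values in brackets. MAGEA6, a cancer-testis antigen, went from 2.36 ± 0.04 to 11.53 ± 1.17, a rise of 9.17 ± 0.47 (adjusted p = 2.56e-05). Among the 10 largest rises were also SSX1 at 9.34 ± 0.60, MAGEA12 at 8.94 ± 0.65, the transketolase-like gene TKTL1 at 8.76 ± 0.60, SSX3 at 8.32 ± 0.55 and the galectin-3 binding protein gene LGALS3BP at 7.84 ± 0.71. The 5 largest falls were smaller: AGAP4 changed by -2.13 ± 0.30 (adjusted p = 0.00519), SPOPL by -1.96 ± 0.35 (0.0168), the growth factor gene VEGFB by -1.92 ± 0.40 (0.0316), the phosphatase gene PTPN9 by -1.92 ± 0.43 (0.0413) and TMEM133 by -1.88 ± 0.43 (0.0412). With replicate number as a block, the adjusted p-values of VEGFB, PTPN9 and TMEM133 were 0.0820, 0.127 and 0.0569. Untreated levels of the genes that rose most were 2 to 4, at the lower end of the scale, where fold changes are uncertain.

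Of 40 interferon-stimulated genes measured in L428, 39 rose, and 40 rose when adjusted over the list alone. The median change was 3.64, camera gave an adjusted p = 2.76e-58, and the adjusted p = 0.0532 with an estimated correlation. PARP9 rose by 3.97 ± 0.23 (adjusted p = 4.37e-05), the oligoadenylate synthetase gene OAS2 by 5.93 ± 0.40 (1.12e-04) and IFIT1, which binds foreign RNA, by 6.48 ± 0.48 (2.05e-04). The mean level of the list was 11.38 in treated replicate 1 and 12.79 and 12.66 in treated replicates 2 and 3, against 7.72 to 8.11 without treatment. Of 18 genes of MHC class I presentation, 7 rose and 13 rose when adjusted over the list alone (median 0.56, camera adjusted p = 4.52e-13, adjusted p = 0.0532 with an estimated correlation). The immunoproteasome genes PSMB9 and PSMB8 rose by 1.33 ± 0.09 (1.37e-04) and 1.21 ± 0.12 (6.72e-04). HLA-E rose by 1.58 ± 0.25 (0.0106), a call that was lost without treated replicate 3 (0.0521) and with replicate number as a block (0.0576). Of 14 genes of MHC class II presentation, 2 rose, also when adjusted over the list alone (median 0.31, camera adjusted p = 0.00924, adjusted p = 0.356 with an estimated correlation). They were HLA-DOB at 1.76 ± 0.30 and the protease gene CTSS at 1.22 ± 0.28, with adjusted p-values of 0.0144 and 0.0455, or 0.0794 and 0.0604 with the block.

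Of 28 cancer-testis antigens measured in L428, 11 rose and 17 were not called, and 21 rose when adjusted over the list alone. The median change was 2.28, the camera adjusted p = 4.19e-22, and the adjusted p = 0.0910 with an estimated correlation. CTCFL, a germ-line paralogue of the insulator protein CTCF, rose by 4.22 ± 0.20 (adjusted p = 1.83e-05), beside MAGEA6 and SSX1. The mean level of the list was 5.73 in treated replicate 1 and 7.59 and 7.75 in treated replicates 2 and 3, against 3.66 to 3.83 without treatment. Of 29 germline and meiosis genes, 9 rose and 10 rose when adjusted over the list alone (median 0.05, camera adjusted p = 6.49e-07, adjusted p = 0.0910 with an estimated correlation). The meiotic gene HORMAD1 rose by 6.08 ± 0.38 (8.03e-05), the germ-cell RNA-binding gene DAZL by 7.76 ± 0.67 (4.84e-04) and the piRNA pathway gene MAEL by 6.07 ± 0.56 (5.79e-04).

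Of 36 NF-kappaB targets, 6 rose and 15 rose when adjusted over the list alone (median 0.88, camera adjusted p = 8.39e-10, adjusted p = 0.280 with an estimated correlation). The chemokine gene CXCL10 rose by 4.68 ± 0.42 (5.45e-04). CCL5 and the inhibitor gene NFKBIE rose by 1.52 ± 0.29 (0.0217) and 0.98 ± 0.19 (0.0217), and both calls were lost with the block (0.0706 and 0.0907). Of 35 JAK-STAT genes, 4 rose, and 9 rose and 4 fell when adjusted over the list alone (median 0.22, camera adjusted p = 0.00317, adjusted p = 0.203 with an estimated correlation). SOCS2, a feedback inhibitor, rose by 1.32 ± 0.20 and the kinase gene JAK2 by 1.05 ± 0.18, with adjusted p-values of 0.00708 and 0.0152, or 0.0515 and 0.0766 with the block. Of 29 MAPK and AP-1 response genes, 2 rose and 1 fell, also when adjusted over the list alone (median 0.43, camera adjusted p = 0.00112, adjusted p = 0.356 with an estimated correlation). DUSP5, a phosphatase that acts on ERK, rose by 3.52 ± 0.77 (0.0368), and the ERK pathway inhibitor SPRY2 changed by -0.38 ± 0.07 (0.0194, or 0.0777 with the block). Without the arrays numbered 1, 22 NF-kappaB targets, 14 JAK-STAT genes and 15 MAPK and AP-1 response genes rose in L428, and 1, 4 and 2 fell.

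Of 33 B-cell programme genes in L428, 4 rose and 5 rose when adjusted over the list alone (median 0.02, camera adjusted p = 0.00924, adjusted p = 0.0653 with an estimated correlation). The complement receptor gene CR2 rose by 2.91 ± 0.10 (2.78e-06) and CD38, an ectoenzyme also on the plasma-cell list, by 5.82 ± 0.74 (0.00302). CD38 was the 1 of 12 plasma-cell genes that rose. Adjusted over the list alone, 2 rose and 1 fell, with a median of -0.0028, a mean of 0.54 and a camera adjusted p = 0.523. Of 23 Hodgkin Reed-Sternberg cell markers, 3 rose and 4 rose when adjusted over the list alone (median 0.22, camera adjusted p = 0.00666, adjusted p = 0.267 with an estimated correlation). These were CCL5, the checkpoint ligand CD274 at 2.64 ± 0.58 (0.0377) and the chemokine CCL22 at 3.76 ± 0.86 (0.0433). With the block, CD274 and CCL22 had adjusted p-values of 0.0714 and 0.125.

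Of 21 pro-death genes, 5 rose and 8 rose when adjusted over the list alone (median 0.59, camera adjusted p = 1.91e-05, adjusted p = 0.0532 with an estimated correlation). The BH3-only gene BIK rose by 2.89 ± 0.27 (6.13e-04), the death ligand TNFSF10 by 1.49 ± 0.27 (0.0178), and BID by 2.40 ± 0.44 (0.0179, or 0.0692 with the block). Of 16 pro-survival genes, limma called 0, with 8 at an unadjusted p under 0.05, and 5 higher and 2 lower when adjusted over the list alone. Their median change was 0.41, the camera adjusted p = 0.0388, the adjusted p = 0.267 with an estimated correlation and 0.0978 with the block, and fry gave 0.0990. The kinase gene PIM2 had a change of 0.99 ± 0.23 (0.0506) and the caspase-8 inhibitor CFLAR one of 0.67 ± 0.17 (0.0620). Of 24 p53 targets, 2 rose and 1 fell, or 3 and 1 when adjusted over the list alone (median -0.02, mean 0.22, camera adjusted p = 0.337). The exonuclease gene AEN rose by 1.49 ± 0.25 (0.0132) and the ubiquitin ligase gene MDM2 changed by -0.60 ± 0.14 (0.0423). Of 6 CDK inhibitors, CDKN1A rose, by 2.46 ± 0.58 (0.0472, or 0.0817 with the block), and 2 rose when adjusted over the list alone (median 0.52, camera adjusted p = 0.0139, adjusted p = 0.203 with an estimated correlation). Of 39 cell-cycle and replication genes, limma called 0, with 5 at an unadjusted p under 0.05 and 0 when adjusted over the list alone (median -0.07, camera adjusted p = 0.944, fry 0.795). CDC45, a replication factor, had a change of 0.53 ± 0.16 (0.0998).

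Of 16 imprinted genes in L428, 2 rose, MEST by 2.21 ± 0.43 (0.0246) and NDN by 2.66 ± 0.57 (0.0345, or 0.0692 with the block). Adjusted over the list alone, 3 rose and 1 fell (median 0.10, camera adjusted p = 0.122). Of 22 genes of DNA methylation and decitabine metabolism, 1 rose and 1 fell, also when adjusted over the list alone (median -0.07, mean 0.001, camera adjusted p = 0.882). SAMHD1, which cleaves deoxynucleotides and the active form of decitabine, rose by 1.71 ± 0.37 (0.0370), and the dioxygenase gene TET3 changed by -0.67 ± 0.14 (0.0272, or 0.0585 with the block). Of 7 endogenous retroviral envelope genes, limma called 0 in either line, with 0 at an unadjusted p under 0.05. Their medians were -0.01 in L428 and -0.02 in L1236, with camera adjusted p-values of 0.969 and 0.631 and fry adjusted p-values of 0.795 and 0.143. In L428 the mean was -0.02 while the camera direction was up. The mean level of this list was 2.55 to 2.93 over the arrays, near the floor. Whether its probe sets detect these genes is unknown, so the absence of calls says little of their induction. Of 11 housekeeping genes, limma called 0 in either line, with 0 at an unadjusted p under 0.05 in L428 and 2 in L1236, and fry gave 0.364 and 0.329. Their medians were -0.12 in each line, with camera adjusted p-values of 0.397 and 0.494. Without the arrays numbered 1, 6 of the 11 fell in each line (medians -0.26 and -0.27), and camera called the list in L428 (0.0443, and 0.0289 with array weights).

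Markers of other cell types moved in a few members in L428. Of 20 T-cell and NK-cell markers, 2 rose and 3 rose when adjusted over the list alone (median -0.01, mean 0.31, camera adjusted p = 0.122). They were the adhesion receptor CD2 at 1.71 ± 0.26 (0.00818) and the transcription factor TBX21 at 2.46 ± 0.39 (0.01). Of 16 myeloid markers, 2 rose, also when adjusted over the list alone (median -0.01, mean 0.40, camera adjusted p = 0.223), with the adaptor gene TYROBP at 4.08 ± 0.22 (2.94e-05) and AIF1 at 1.39 ± 0.30 (0.0351, or 0.0815 with the block). Without the dimmest genes the myeloid list had a median of 0.14 and a camera adjusted p = 0.0194. Of 16 stromal, endothelial and epithelial markers, 2 rose and 3 rose when adjusted over the list alone (median 0.004, camera adjusted p = 0.0474, adjusted p = 0.356 with an estimated correlation). The surface glycoprotein THY1 rose by 1.34 ± 0.23 (0.0142) and the cadherin gene CDH1 by 2.66 ± 0.58 (0.0362).

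For L428, limma called 920 of 19775 genes, 656 higher and 264 lower, and 565 of these changed at least 2-fold, 506 higher and 59 lower. With only the arrays of L428 in the fit, it called 206. Of the 506, 235 (46.4%) had an untreated level below the median of all genes. Among the lists, camera called 14 of 23, and with an estimated correlation it called 0, with 6 at an unadjusted p under 0.05. At the preset correlation, other splits of the same arrays gave up to 10 called lists. Fry called 6, and not NF-kappaB targets (0.0765), JAK-STAT genes (0.0655), MAPK and AP-1 genes (0.222), Hodgkin Reed-Sternberg cell markers (0.106), MHC class II genes (0.171), CDK inhibitors (0.0725), stromal markers (0.153) or pro-survival genes. The number of genes depended on single arrays: it was 3532 without treated replicate 1, 388 and 368 without treated replicate 2 or 3, and 472 and 456 without untreated replicate 2 or 3. It was 5717 without all arrays numbered 1, 2838 higher and 2879 lower (49.6% higher against 71.3%), including 899 of the 920. In that setting 23 cancer-testis antigens, 13 MHC class I genes and 12 pro-death genes rose, and the numbers that rose and fell were 2 and 11 for cell-cycle genes, 8 and 2 for pro-survival genes, 7 and 5 for p53 targets and 10 and 1 for Hodgkin Reed-Sternberg cell markers. With single arrays left out, 28 of 56 named calls were lost in 1 case or another. Without treated replicate 1, camera no longer called the lists of JAK-STAT genes (adjusted p = 0.0902), B-cell genes (0.0915), MHC class II genes (0.321), CDK inhibitors (0.0838), pro-survival genes (0.0902) and stromal markers (0.0915). Without untreated replicate 2 it no longer called JAK-STAT genes (0.0744), MHC class II genes (0.125), CDK inhibitors (0.0763) and pro-survival genes (0.0763), and without untreated replicate 1 Hodgkin Reed-Sternberg cell markers (0.0503) and stromal markers (0.132). Stromal markers were also not called without untreated replicate 3 (0.0772) or treated replicate 2 (0.0748), with median centring (0.0734) or with cyclic loess (0.0667). Pro-survival genes were also not called without treated replicate 2 (0.0705) or 3 (0.0697), or with cyclic loess (0.110). Without the dimmest genes the lists of pro-survival genes (0.132), MHC class II genes (0.0526) and CDK inhibitors (0.0526) were not called. Imprinted genes were called without treated replicate 1 (0.0437) or all arrays numbered 1 (0.0390), and stromal markers were not called in the latter setting (0.126).

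**Figure D1:**
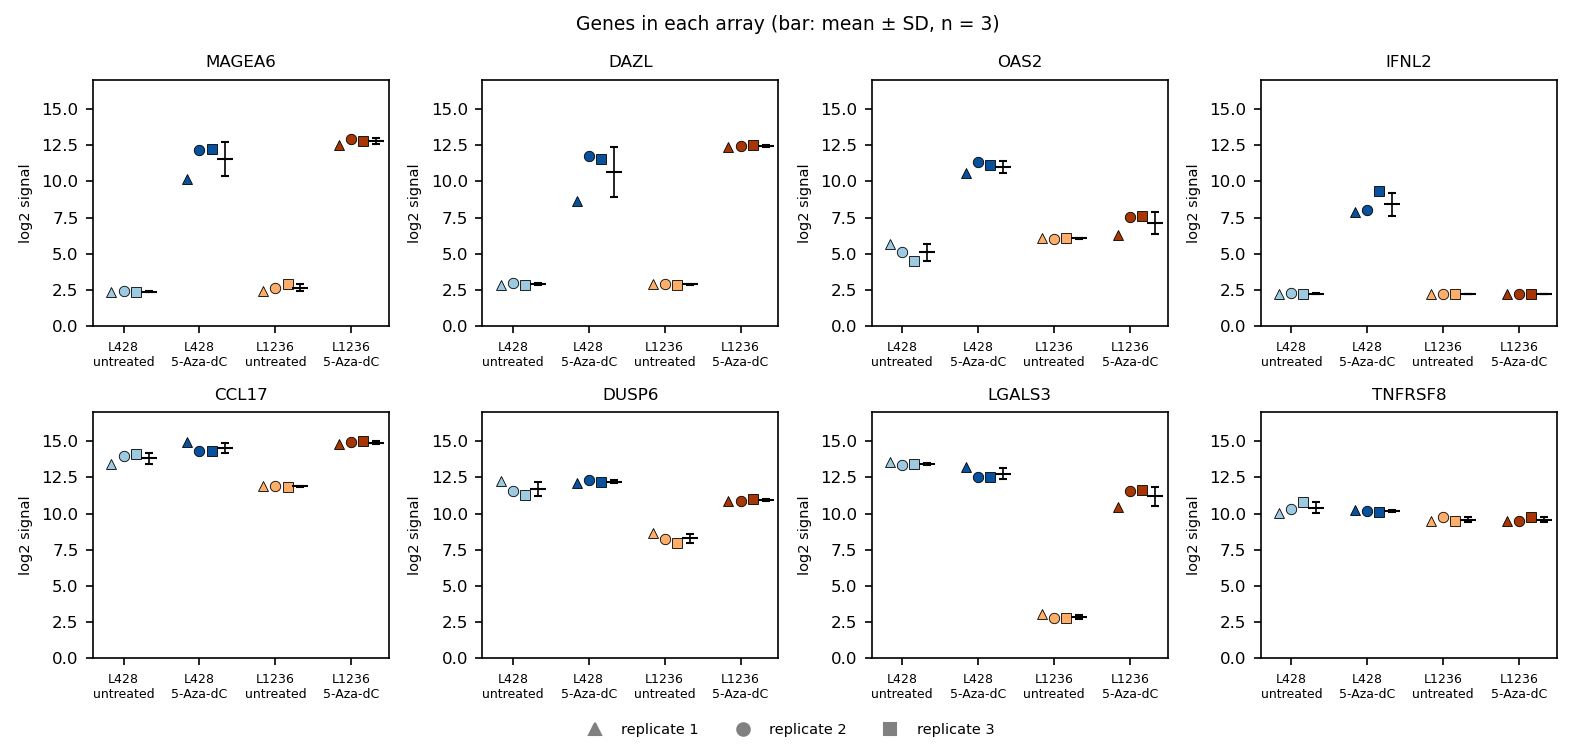
Log2 signal of 8 genes in each of the 12 arrays, with groups on the horizontal axis, symbols for the replicate number and bars for mean ± SD (n = 3). MAGEA6 and DAZL were at 2.36 to 2.90 in both untreated groups and at 10.64 or higher on average after treatment, IFNL2 rose in L428 and LGALS3 in L1236, and TNFRSF8 was 9.57 to 10.39 in all groups.

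In L1236, the 10 largest rises held cancer-testis antigens and germ-cell genes. MAGEA6 went from 2.65 ± 0.24 to 12.76 ± 0.21, a rise of 10.11 ± 0.47 (adjusted p = 2.82e-06), and DAZL from 2.90 ± 0.03 to 12.41 ± 0.07, a rise of 9.51 ± 0.67 (4.05e-05). TKTL1 rose by 10.04 ± 0.60, CTAG2, which encodes a cancer-testis antigen, by 8.89 ± 0.51, the germ-cell gene GCNA by 8.89 ± 0.41 and MAGEA12 by 8.75 ± 0.65. The largest rises also held genes outside the germ line: ITIH3 at 8.69 ± 0.26, the calcium-binding protein gene S100A11 at 8.35 ± 0.29, the galectin gene LGALS3 at 8.33 ± 0.30 and the connexin gene GJB2 at 8.26 ± 0.17. The largest falls were those of the globin gene HBD at -5.29 ± 0.71 (0.00175), the phosphatase gene PTPRR at -5.13 ± 0.55 (5.41e-04), SH3D19 at -4.35 ± 0.70 (0.00435), SLITRK6 at -4.31 ± 0.59 (0.00183) and PDZRN3 at -4.12 ± 0.44 (5.40e-04).

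Of 28 cancer-testis antigens in L1236, 17 rose and 1 fell, or 19 and 1 when adjusted over the list alone (median 2.83, camera adjusted p = 2.50e-14, adjusted p = 0.135 with an estimated correlation). CTCFL rose by 4.38 ± 0.20 (2.66e-06). Of 29 germline and meiosis genes, 13 rose, also when adjusted over the list alone (median 0.12, camera adjusted p = 1.76e-06, adjusted p = 0.106 with an estimated correlation). HORMAD1 rose by 7.98 ± 0.38 (3.07e-06) and the piRNA-binding gene PIWIL2 by 2.94 ± 0.20 (3.35e-05). Of 40 interferon-stimulated genes, 20 rose and 29 rose when adjusted over the list alone (median 1.55, camera adjusted p = 9.16e-17, adjusted p = 0.162 with an estimated correlation). CMPK2 rose by 5.10 ± 0.66 (0.00144), OAS3 by 3.01 ± 0.40 (0.00156) and IFITM3, which blocks viral entry, by 3.21 ± 0.42 (0.00159). The mean level of the interferon-stimulated list was 8.83 in treated replicate 1 and 10.09 and 10.03 in treated replicates 2 and 3, against 7.52 to 7.85 without treatment. Of 18 MHC class I genes, 7 rose, and 8 rose and 1 fell when adjusted over the list alone (median 0.38, camera adjusted p = 2.42e-05, adjusted p = 0.135 with an estimated correlation). HLA-B and HLA-E rose by 1.40 ± 0.21 (0.00276) and 1.66 ± 0.25 (0.00328), and PSMB9 by 0.64 ± 0.09 (0.00241). Of 14 MHC class II genes, limma called 0, with 4 at an unadjusted p under 0.05 and 0 when adjusted over the list alone. Their median was -0.14 and their mean 0.02, with a camera adjusted p = 0.631 in the upward and a fry adjusted p = 0.978 in the downward direction. HLA-DOB had a change of 1.03 ± 0.30 (0.0532).

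Of 36 NF-kappaB targets in L1236, 18 rose and 30 rose when adjusted over the list alone (median 1.63, camera adjusted p = 2.25e-15, adjusted p = 0.135 with an estimated correlation). The feedback inhibitor TNFAIP3 rose by 2.37 ± 0.29 (0.00102), the cytokine LTA by 2.78 ± 0.34 (0.00105) and CCL5 by 2.24 ± 0.29 (0.00144). The mean level of the list was 9.75 in treated replicate 1, 11.17 and 11.29 in treated replicates 2 and 3, and 8.64 to 9.02 without treatment. Of 35 JAK-STAT genes, 14 rose, and 15 rose and 1 fell when adjusted over the list alone (median 0.59, camera adjusted p = 2.14e-06, adjusted p = 0.1 with an estimated correlation). The chemokine gene CCL17 went from 11.90 ± 0.03 to 14.90 ± 0.11, a rise of 3.01 ± 0.20 (2.68e-05). The transcription factor STAT3 rose by 1.24 ± 0.13 (4.83e-04) and the cytokine IL13 by 6.53 ± 0.82 (0.00120). Of 29 MAPK and AP-1 response genes, 18 rose and 24 rose when adjusted over the list alone (median 1.71, camera adjusted p = 2.46e-13, adjusted p = 0.106 with an estimated correlation). The ERK phosphatase DUSP6 rose by 2.65 ± 0.24 (2.08e-04), PHLDA1 by 3.88 ± 0.38 (3.41e-04) and the AP-1 subunit FOSB by 2.83 ± 0.46 (0.00437). The mean level of the MAPK and AP-1 list was 8.62 in treated replicate 1 and 9.60 and 9.62 in treated replicates 2 and 3.

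Of 23 Hodgkin Reed-Sternberg cell markers in L1236, 11 rose and 12 rose when adjusted over the list alone (median 0.80, camera adjusted p = 2.64e-08, adjusted p = 0.1 with an estimated correlation). Beside CCL17 and IL13, the galectin LGALS1 rose by 0.84 ± 0.10 (0.00103). Of 33 B-cell programme genes, 5 rose and 1 fell, also when adjusted over the list alone (median 0.03, camera adjusted p = 0.161, fry 0.00808). SPIB, an ETS factor of B cells, rose by 6.54 ± 0.31 (3.07e-06), the receptor CD72 by 0.97 ± 0.13 (0.00191), and CD27 changed by -1.47 ± 0.11 (5.63e-05). CD72 was only at 3.40 to 4.01 in the treated arrays, low on the scale. Of 12 plasma-cell genes, 2 rose and 1 fell, or 2 and 2 when adjusted over the list alone (median 0.04, camera adjusted p = 0.207, fry 1.10e-04). The plasma-cell regulator PRDM1 rose by 1.65 ± 0.10 (1.16e-05) and MZB1 changed by -1.10 ± 0.30 (0.0376), a call lost without any 1 of the 6 arrays, up to 0.116, and with the block (0.117).

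Of 21 pro-death genes in L1236, 6 rose, and 9 rose and 2 fell when adjusted over the list alone. Their median was -0.03 and their mean 0.35, with a camera adjusted p = 0.0594 and a fry adjusted p = 0.0176. The camera value was 0.0311 with median centring, 0.0317 without untreated replicate 1 and 0.0443 without treated replicate 1. DAPK1, a kinase that promotes cell death, rose by 2.57 ± 0.27 (4.90e-04). Of 16 pro-survival genes, 4 rose and 1 fell, or 5 and 1 when adjusted over the list alone (median 0.44, camera adjusted p = 0.0229, adjusted p = 0.162 with an estimated correlation). CFLAR rose by 1.18 ± 0.17 (0.00242), the BCL2 relative BCL2A1 by 3.55 ± 0.52 (0.00273), and the kinase gene AKT2 changed by -1.21 ± 0.19 (0.00355). This list's call was lost with cyclic loess (0.0696), without the dimmest genes (0.0883) and without treated replicate 3 (0.0540). Of 24 p53 targets, 8 rose and 2 fell, or 10 and 7 when adjusted over the list alone (median 0.28, camera adjusted p = 0.0416, adjusted p = 0.106 with an estimated correlation). AEN rose by 1.71 ± 0.25 (0.00283), TP53I3 by 2.71 ± 0.41 (0.00330) and TP53INP1 by 2.93 ± 0.48 (0.00446). This call was lost with cyclic loess (0.141), with the block (0.129), without the dimmest genes (0.149), and without untreated replicate 2 or 3 or treated replicate 2 or 3 (0.0758, 0.0778, 0.0770 and 0.0540). Of 6 CDK inhibitors, 3 rose, and 3 rose and 1 fell when adjusted over the list alone (median 1.37, camera adjusted p = 0.00356, adjusted p = 0.106 with an estimated correlation). CDKN1C rose by 3.25 ± 0.31 (3.01e-04), CDKN2D by 1.77 ± 0.22 (0.00117) and CDKN1A by 3.26 ± 0.58 (0.00652). Of 39 cell-cycle and replication genes, 2 rose and 3 fell, also when adjusted over the list alone (median -0.30, camera adjusted p = 0.161). CDC45 rose by 1.16 ± 0.16 (0.00183), and the helicase subunit MCM6 changed by -0.75 ± 0.18 (0.0263). Without treated replicate 1 the cell-cycle list had a median of -0.57 and a camera adjusted p = 1.68e-04. Without the arrays numbered 1, 3 of the 39 rose and 29 fell (-0.61, 2.05e-05). These camera values use the preset correlation, while the estimated correlation of this list was 0.503. With all arrays the adjusted p was 0.759 with the estimated correlation and 0.329 with fry.

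Of 16 imprinted genes in L1236, 3 rose and 1 fell, also when adjusted over the list alone (median -0.03, mean 0.64, camera adjusted p = 0.161), with PEG3 at 4.51 ± 0.84 (0.00831) and SGCE at -0.61 ± 0.14 (0.0211). Of 22 genes of DNA methylation and decitabine metabolism, 2 rose and 3 fell, or 4 and 8 when adjusted over the list alone (median -0.25, camera adjusted p = 0.361, fry 0.00812 in the downward direction). Of these, 4 rose and 10 fell without the arrays numbered 1. The methyl-CpG binding gene ZBTB4 changed by -1.04 ± 0.22 (0.0150) and the glycosylase gene MBD4 rose by 0.43 ± 0.11 (0.0284, or 0.0554 with the block). Of 20 T-cell and NK-cell markers, 6 rose, and 8 rose and 1 fell when adjusted over the list alone (median 0.54, camera adjusted p = 2.76e-04, adjusted p = 0.1 with an estimated correlation). CD8A rose from 1.97 ± 0.02 to 5.33 ± 0.42, by 3.36 ± 0.17 (3.65e-06), and the kinase genes ZAP70 and LCK rose by 2.08 ± 0.15 (4.58e-05) and 1.69 ± 0.22 (0.00156). ZAP70 and LCK were only at 4.13 to 4.77 and 3.37 to 4.52 in the treated arrays, low on the scale. Of 16 myeloid markers, 3 rose, also when adjusted over the list alone (median -0.02, mean 0.67, camera adjusted p = 0.156, fry 0.00812). Without the dimmest genes the median was 0.61 and the camera adjusted p = 0.00395. TYROBP rose by 6.04 ± 0.22 (4.65e-07), ITGAM by 1.63 ± 0.16 (3.53e-04) and AIF1 by 2.17 ± 0.30 (0.00196). Of 16 stromal, endothelial and epithelial markers, 6 rose and 7 rose when adjusted over the list alone (median 0.80, camera adjusted p = 1.63e-05, adjusted p = 0.106 with an estimated correlation). The adhesion molecule EPCAM rose from 2.83 ± 0.01 to 8.20 ± 0.24, by 5.37 ± 0.10 (4.08e-09), THY1 by 5.95 ± 0.23 (7.40e-07) and the keratin gene KRT19 by 2.03 ± 0.11 (8.99e-06).

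For L1236, limma called 2955 genes, 1699 higher and 1256 lower, and 1675 of these changed at least 2-fold, 1132 higher and 543 lower. With median centring the split was 1742 higher and 2066 lower, a share of 45.7% higher against 57.5%. Of the 1132, 613 (54.2%) had an untreated level below the median of all genes. Among the lists, camera called 13 of 23, and with an estimated correlation it called 0, with 8 at an unadjusted p under 0.05, while fry called 18. At the preset correlation, other splits of the same arrays gave up to 12 called lists. The number of genes was 4488 without treated replicate 1, 1512 and 1554 without treated replicate 2 or 3, and 1662 and 1506 without untreated replicate 2 or 3. It was 6817 without all arrays numbered 1, 3312 higher and 3505 lower, including 2821 of the 2955. In that setting 32 NF-kappaB targets, 22 cancer-testis antigens and 12 MHC class I genes rose, and the numbers that rose and fell were 3 and 5 for MHC class II genes, 19 and 5 for JAK-STAT genes, 10 and 2 for pro-death genes and 11 and 6 for p53 targets. With single arrays left out, 12 of 71 named calls were lost in 1 case or another.

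**Figure D2:**
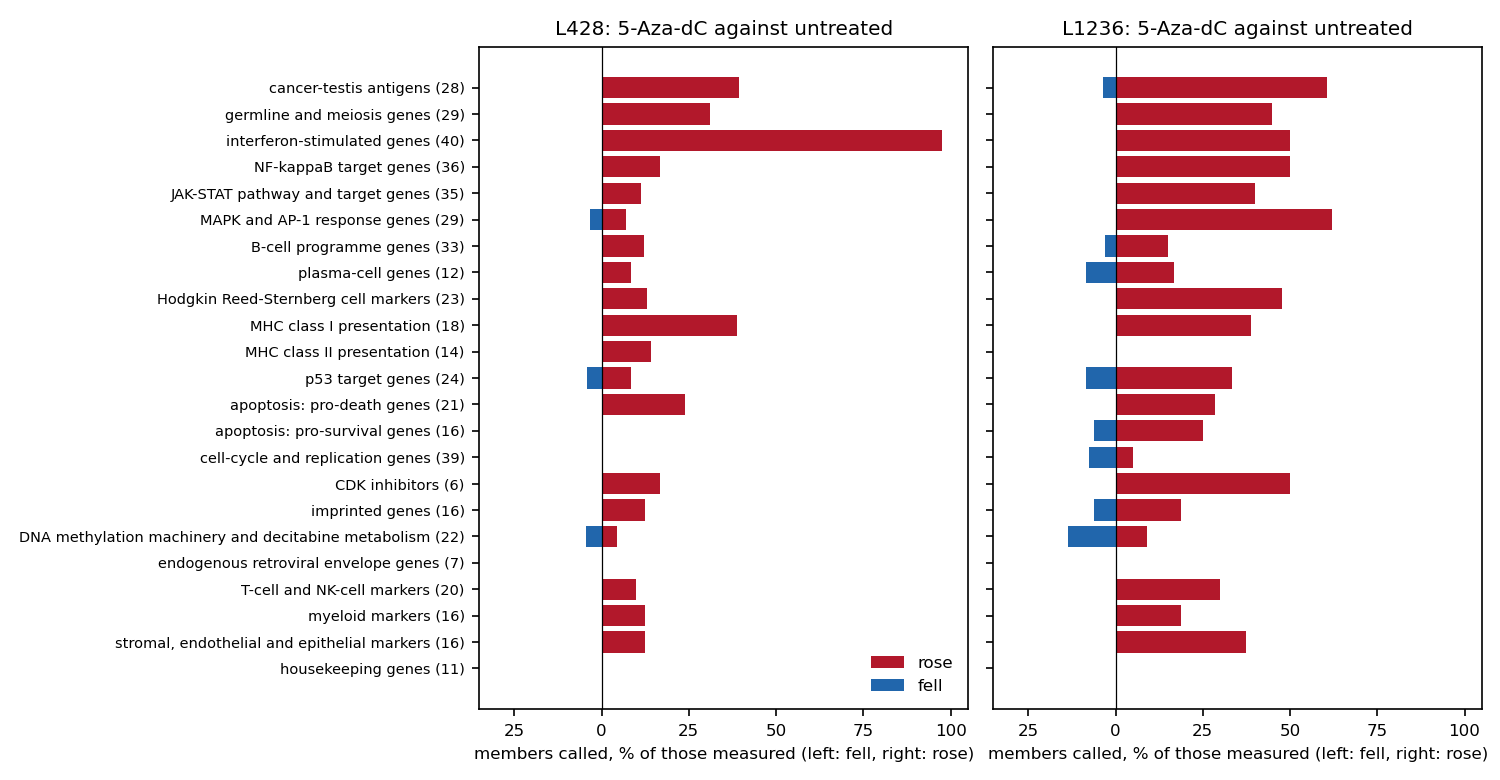
Share of the measured members of each gene list that limma called higher (right, red) or lower (left, blue) after 5-Aza-dC, in percent, with L428 on the left and L1236 on the right and the number of measured members in brackets. Interferon-stimulated genes rose in 39 of 40 cases in L428 and 20 of 40 in L1236 (40 and 37 without the arrays numbered 1), and MAPK and AP-1 response genes in 2 and 18 of 29 (15 and 25 without those arrays).

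The genes fixed for every comparison changed as follows. DNMT1, the maintenance methyltransferase, had a change of -0.38 ± 0.14 in L428 (adjusted p = 0.159) and changed by -0.57 ± 0.14 in L1236 (0.0241). DNMT3A had a change of 1.02 ± 0.46 in L428 (0.272) and rose by 1.75 ± 0.46 in L1236 (0.0358, or 0.0832 with the block), and DNMT3B had changes of 0.62 ± 0.18 (0.1) and 0.60 ± 0.18 (0.0585). TNFRSF8, which encodes the Hodgkin marker CD30, was at 10.39 ± 0.38 and 10.18 ± 0.09 in L428 and at 9.57 ± 0.16 and 9.59 ± 0.15 in L1236, with adjusted p-values of 0.572 and 0.945. MYC rose by 1.12 ± 0.25 in L428 (0.0408, or 0.0924 with the block) and by 1.09 ± 0.25 in L1236 (0.0220, or 0.0611 with it). The anti-apoptotic gene BCL2 had changes of 2.23 ± 0.69 (0.115) and 1.06 ± 0.69 (0.333). The calls of DNMT1, DNMT3A and MYC in L1236, and of MYC and CDKN1A in L428, were each lost without 4 or 5 of the 6 arrays, up to 0.0936, 0.126, 0.0873, 0.165 and 0.187.

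LGALS3 was at 13.44 ± 0.08 in untreated L428 and at 2.87 ± 0.15 in untreated L1236, where it reached 11.20 ± 0.64, and its responses differed by 9.02 ± 0.43 (adjusted p = 5.68e-06). S100A11 likewise started at 11.48 ± 0.32 in L428 and at 2.87 ± 0.21 in L1236, GJB2 was at 11.43 ± 0.11 in untreated L428, and the responses of GJB2 and S100A11 differed by 8.13 ± 0.25 (3.72e-07) and 7.63 ± 0.41 (1.37e-05). ITIH3 was near 2.01 in both untreated lines and rose in L1236, with a difference of 8.70 ± 0.37 (3.42e-06). In the other direction, the actin-bundling gene PLS3 differed by -6.93 ± 0.54 (1.93e-04), the histone gene H2AC6 by -6.82 ± 1.10 (0.0112), the interferon gene IFNL2 by -6.20 ± 0.44 (1.09e-04), SSX1 by -6.05 ± 0.85 (0.00591) and the germ-cell cyclin gene CCNA1 by -6.02 ± 1.22 (0.0285). PLS3, H2AC6 and SSX1 were already at 10.35, 11.16 and 9.76 in untreated L1236, against 2.67, 3.80 and 2.68 in untreated L428. H2AC6 and CCNA1 had adjusted p-values of 0.0731 and 0.0811 with the block, and CCNA1 lost its call without any 1 of 8 arrays, up to 0.0747.

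Of 40 interferon-stimulated genes, 16 had a smaller response in L1236 than in L428, and 30 when adjusted over the list alone (median difference -2.04, camera adjusted p = 2.55e-19, adjusted p = 0.385 with an estimated correlation). IFIT1 differed by -5.04 ± 0.68 (0.00471), OAS2 by -4.87 ± 0.56 (0.00212) and PARP9 by -2.78 ± 0.32 (0.00212). Of 29 MAPK and AP-1 response genes, 3 had a larger response in L1236, and 7 when adjusted over the list alone (0.74, camera adjusted p = 7.29e-07, adjusted p = 0.385 with an estimated correlation), with PHLDA1 at 3.57 ± 0.54 (0.00879) and DUSP6 at 2.13 ± 0.34 (0.0108). Of 36 NF-kappaB targets, 2 had a larger and 1 a smaller response in L1236, or 4 and 1 when adjusted over the list alone (0.85, camera adjusted p = 6.98e-04, adjusted p = 0.709 with an estimated correlation). TNFAIP3 was among the former at 1.98 ± 0.41 (0.0299) and CXCL10 was the latter at -3.40 ± 0.60 (0.0164). Without treated L428 replicate 1 this list's camera adjusted p was 0.114. Of 23 Hodgkin Reed-Sternberg cell markers, 3 had a larger response in L1236, and 5 when adjusted over the list alone (0.72, camera adjusted p = 1.63e-04, adjusted p = 0.385 with an estimated correlation), with CCL17 at 2.29 ± 0.28 (0.00298). Of 35 JAK-STAT genes, 4 had a larger and 1 a smaller response, or 6 and 2 when adjusted over the list alone (0.38, camera adjusted p = 0.0108, adjusted p = 0.385 with an estimated correlation), with STAT3 at 1.31 ± 0.18 (0.00566) and JAK2 at -1.49 ± 0.26 (0.0159). This call was lost without untreated L428 replicate 1 (0.0723). PHLDA1, DUSP6, TNFAIP3, STAT3 and CCL17 started higher in L428, where all untreated arrays lay above those of untreated L1236. Without the arrays numbered 1, the members with larger and smaller responses in L1236 were 2 and 33 for interferon-stimulated genes, 19 and 0 for MAPK and AP-1 response genes, 24 and 4 for NF-kappaB targets, 13 and 1 for Hodgkin Reed-Sternberg cell markers, and 14 and 5 for JAK-STAT genes.

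Of 29 germline and meiosis genes, 3 had a larger response in L1236, and 5 a larger and 1 a smaller one when adjusted over the list alone (0.15, camera adjusted p = 0.0108, adjusted p = 0.430 with an estimated correlation), with PIWIL2 at 2.37 ± 0.29 (0.00271). PIWIL2 started at 7.32 to 7.75 in untreated L428 and at 4.88 to 5.67 in untreated L1236. Of 28 cancer-testis antigens, 1 had a larger and 3 a smaller response in L1236, or 2 and 3 when adjusted over the list alone, and 8 and 11 without the arrays numbered 1 (median 0.10, mean -0.11, camera adjusted p = 0.664). Of 16 stromal, endothelial and epithelial markers, 5 had a larger response in L1236, and 6 when adjusted over the list alone (0.04, camera adjusted p = 2.81e-04, adjusted p = 0.385 with an estimated correlation), with EPCAM at 5.39 ± 0.14 (1.02e-07). Of 20 T-cell and NK-cell markers, 4 had a larger response, also when adjusted over the list alone (0.03, camera adjusted p = 0.0324, adjusted p = 0.385 with an estimated correlation), with CD8A at 3.37 ± 0.23 (9.15e-05). This call was lost with the block (0.102), with cyclic loess (0.0698), without the dimmest genes (0.179), and without treated L428 replicate 1 or untreated L1236 replicate 1 (0.109 and 0.0584). Fry called 7 lists for the difference and not NF-kappaB targets (0.303), MAPK and AP-1 genes (0.0504) or germline genes (0.0504). Among its calls were B-cell genes (0.0212, lower in L1236) and plasma-cell genes (0.0173, higher), which camera did not call (0.664 and 0.564). The B-cell difference had a median of 0.01 and a mean of -0.14, and the plasma-cell difference a median of 0.06 and a mean of -0.36. Their directions are therefore uncertain.

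For the difference between the lines, limma called 914 genes, 527 with the higher and 387 with the lower value in L1236, of which 699 differed at least 2-fold. With the replicate number as a block it called 497, 297 higher and 200 lower, and 365 of these were among the 914. The count was 1954 and 2112 without treated replicate 1 of L428 or L1236, and 4697 without all arrays numbered 1, 2252 higher and 2445 lower, including 856 of the 914. Without treated L1236 replicate 1, camera also called the differences, L1236 minus L428, of cell-cycle genes (median -0.42, adjusted p = 3.46e-04) and MHC class II genes (-0.50, 0.0105). It called that of cell-cycle genes (-0.26, 0.00197) and p53 targets (0.35, 0.0318) without the arrays numbered 1. It called MHC class I genes without untreated L428 replicate 3 (-0.37, 0.0318) or treated L1236 replicate 3 (-0.32, 0.0384). All of these list calls use the preset correlation of 0.01. The number of genes was 511 and 497 without untreated L428 replicate 2 or 3, 498 and 494 without treated L428 replicate 2 or 3, 488 and 442 without untreated L1236 replicate 2 or 3, and 539 and 579 without treated L1236 replicate 2 or 3.

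**Figure D3:**
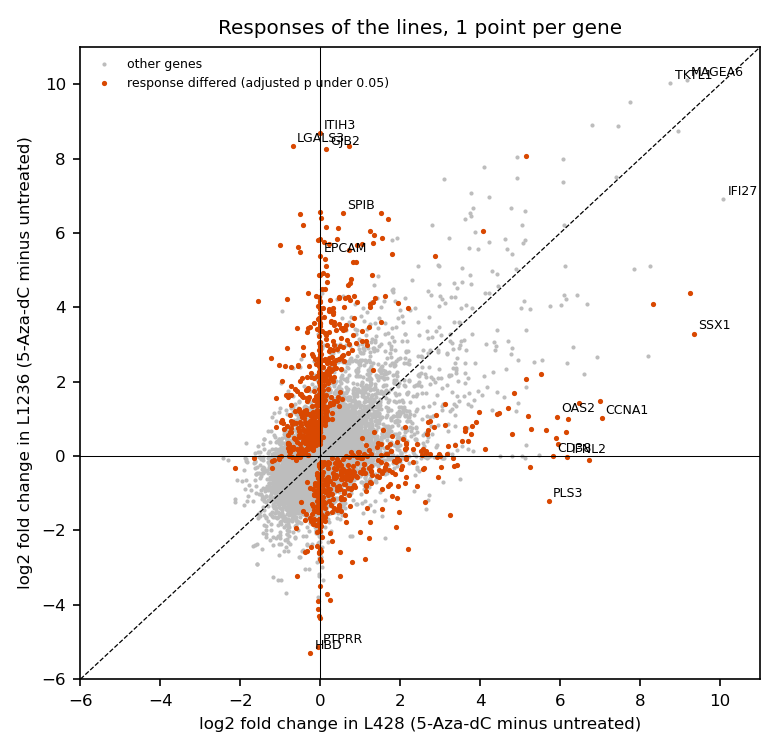
Log2 fold change after 5-Aza-dC in L428 (horizontal axis) against L1236 (vertical axis), 1 point per gene, with orange for the genes whose responses differed and a dashed line for equal responses. Genes such as LGALS3, GJB2 and ITIH3 lay along the vertical axis and PLS3, IFNL2 and CCNA1 along the horizontal axis, while MAGEA6 and TKTL1 lay near the dashed line.

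The largest mean responses among genes called the same way in both lines were those of MAGEA6 at 9.64 ± 0.33 (adjusted p = 5.14e-07), TKTL1 at 9.40 ± 0.42 (2.61e-06), MAGEA12 at 8.84 ± 0.46 (6.86e-06), DAZL at 8.63 ± 0.48 (9.62e-06) and IFI27 at 8.50 ± 0.72 (1.42e-04). The largest mean falls were those of SCAI at -2.24 ± 0.23 (4.73e-04), the sorting gene VPS36 at -1.76 ± 0.21 (9.35e-04), VWA8 at -1.28 ± 0.15 (8.40e-04), the translation factor EIF2A at -1.25 ± 0.20 (0.00355) and POFUT4 at -1.21 ± 0.19 (0.00326). Of the genes called in each line, 264 were higher in both, where independent lists would share 56.4, and 74 were lower in both, against 16.8. A further 12 were higher in L428 and lower in L1236, against 41.7, and 6 the reverse, against 22.7. Without the arrays numbered 1, 1490 genes were higher in both lines, 1609 lower in both, and 537 moved in opposite directions. Across genes the responses correlated at r = 0.514 and rho = 0.425, and no control arrays were shared. For the mean response limma called 3730 genes, 2065 higher and 1665 lower, of which 1349 changed at least 2-fold. With median centring the split was 2161 higher and 2563 lower, a share of 45.7% higher against 55.4%, and without the arrays numbered 1 it was 3792 and 3913. The count was 2426 and 2322 without treated L428 replicate 2 or 3, 2462 without untreated L1236 replicate 3, 2404 without treated L1236 replicate 2, and 7705 without all arrays numbered 1.

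Among the genes that differed between the untreated lines, FCER1A, a chain of the IgE receptor, was at 14.55 ± 0.07 in L1236 and 2.57 ± 0.06 in L428, a difference of 11.98 ± 0.05 (adjusted p = 3.72e-14). The non-coding RNA gene BANCR, the sulfatase gene SULF1, the B-cell coactivator gene POU2AF1 and the receptor gene CD93 were higher in L1236 by 11.50 ± 0.12, 11.14 ± 0.24, 11.02 ± 0.40 and 10.60 ± 0.09. THEMIS, a T-cell signalling gene, was lower in L1236 at -10.78 ± 0.25 (4.42e-09), as were the arginine synthesis gene ASS1 at -10.61 ± 0.39, LGALS3 at -10.57 ± 0.30 and the matrix gene CTHRC1 at -10.41 ± 0.31. Of 14 MHC class II genes, 1 was higher and 11 were lower in L1236, also when adjusted over the list alone (median -1.60, camera adjusted p = 0.00276, adjusted p = 0.921 with an estimated correlation). It was the only list of 23 that camera called for the untreated lines, where fry called 12. Between the untreated lines limma called 5699 genes, 3013 higher and 2686 lower in L1236, of which 3776 differed at least 2-fold.

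**Figure D4:**
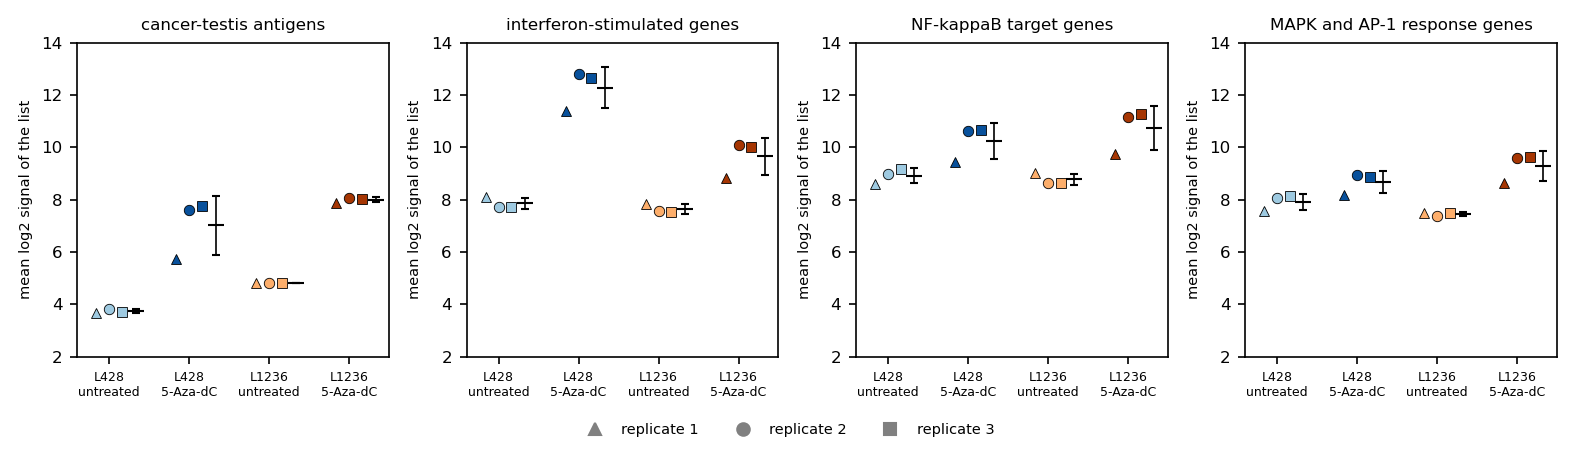
Mean log2 signal of 4 gene lists in each of the 12 arrays, with groups on the horizontal axis, symbols for the replicate number and bars for mean ± SD (n = 3). Treated replicate 1 (triangles) lay below the other treated arrays of its line in each of these lists, as at 11.38 against 12.79 and 12.66 for interferon-stimulated genes in L428.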

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

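Chosen after the results were seen were the tests of a ceiling and of interferon genes, the splits with the mean response taken out, and the setting without the 4 arrays numbered 1, while the other splits of the arrays were planned. A test of the difference between the responses of the lines gave 914 genes and 8 gene lists, and the genes among them that the report names are given here with the L1236 response minus the L428 response (log2).

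Interferon-stimulated genes rose less in L1236, with a median difference of -2.04 over the list (camera adjusted p = 2.55e-19, adjusted p = 0.385 with an estimated correlation). Members and related genes with a smaller response in L1236 were IFIT1 at -5.04, OAS2 at -4.87, TRIM22 at -4.87, PARP9 at -2.78 and the interferon gene IFNL2 at -6.20. Also smaller in L1236 were CXCL10 at -3.40, JAK2 at -1.49, PSMB8 at -1.04 and PSMB9 at -0.69. Outside the interferon response, PLS3 at -6.93, H2AC6 at -6.82, SSX1 at -6.05, SSX3 at -4.23, CCNA1 at -6.02, CD38 at -5.82, CR2 at -2.94 and BIK at -1.80 rose in L428 by more than the change in L1236. Of these, PLS3, H2AC6, SSX1 and SSX3 were already at 10.35, 11.16, 9.76 and 7.60 in untreated L1236 and reached 9.14, 11.05, 13.05 and 11.69 after treatment, against 8.39, 10.51, 12.02 and 11.18 in treated L428, so that their treated levels in L1236 were no lower. PTPRR at -5.08, HBD at -5.04, SH3D19 at -4.33, SLITRK6 at -4.27, PDZRN3 at -4.05 and CD27 at -1.99 fell in L1236. In untreated L428 they were at 3.87, 2.89, 2.33, 2.53, 3.18 and 3.33, near the floor, where they could not fall as far, so these differences say little of a response of L428. In L428, CD27 had a change of 0.52 (adjusted p = 0.0328, or 0.0985 with replicate number as a block).

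Lists with a larger response in L1236 were NF-kappaB targets (median 0.85), MAPK and AP-1 response genes (0.74), Hodgkin Reed-Sternberg cell markers (0.72), JAK-STAT genes (0.38), germline and meiosis genes (0.15), stromal, endothelial and epithelial markers (0.044) and T-cell and NK-cell markers (0.032). With an estimated correlation the adjusted p-values of these 7 lists were 0.385 to 0.709, and the calls of NF-kappaB targets, JAK-STAT genes and T-cell and NK-cell markers were also lost when single arrays were left out (0.114, 0.0723 and 0.109). The signalling and chemokine genes TNFAIP3 at 1.98, DUSP6 at 2.13, PHLDA1 at 3.57, STAT3 at 1.31, CCL17 at 2.29 and IL13 at 5.01 were among the genes that rose more there. All of these but IL13 started higher in L428, with CCL17 at 13.41 to 14.10 in untreated L428 and 11.86 to 11.92 in untreated L1236. Their larger rise in L1236 was thus one from a lower start. Single genes of the cell cycle, p53 response and cell death that rose more in L1236 were CDKN2D at 1.69, CDKN1C at 2.42, DAPK1 at 2.18, TP53I3 at 3.14 and TP53INP1 at 3.36. DAPK1 and TP53I3 were already at 11.3 to 11.9 and 8.5 to 8.7 in untreated L428. For the difference, camera did not call p53 targets (adjusted p = 0.223), CDK inhibitors (0.216) or pro-death genes (0.220). Of the pro-death genes, 1 had a larger and 2 a smaller response in L1236. Lymphoid and myeloid genes with larger responses in L1236 were CD72 at 0.91, PRDM1 at 1.64, LCK at 1.71, ZAP70 at 1.83, CD8A at 3.37, SPIB at 5.98, ITGAM at 1.49 and TYROBP at 1.97. Treated L1236 arrays were only at 3.40 to 4.01 for CD72, 3.37 to 4.52 for LCK and 4.13 to 4.77 for ZAP70. CD8A and ITGAM reached 4.93 to 5.77 and 5.30 to 5.87, and PRDM1, SPIB and TYROBP 7.66 or more. PRDM1 was already at 9.75 to 9.90 in untreated L428, against 5.97 to 6.21 in untreated L1236. Larger and smaller responses in L1236 numbered 2 and 3 for B-cell genes, 1 and 1 for plasma-cell genes and 2 and 0 for myeloid markers. Camera called none of these 3 lists for the difference (adjusted p = 0.664, 0.564 and 0.281). KRT19 at 2.03, THY1 at 4.61, EPCAM at 5.39, PIWIL2 at 2.37 and LGALS1 at 0.83 also rose more in L1236. PIWIL2 and LGALS1 were already at 7.32 to 7.75 and 14.20 to 14.40 in untreated L428. In untreated L1236 they were at 4.88 to 5.67 and 13.02 to 13.35, while KRT19, EPCAM and THY1 did not start higher in L428. Wide differences were also those of LGALS3 at 9.02, ITIH3 at 8.70, GJB2 at 8.13, S100A11 at 7.63, CTHRC1 at 6.69 and ASS1 at 5.70. In untreated L428 all of these but ITIH3, and SPIB, were already at 8.86 or more. AGAP4 at 1.80 stood out because it fell in L428. In untreated L1236 it was at 3.06 to 3.22, near the floor, where it could not fall as far.

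Over the 100 drawn splits of the arrays within each line, 4 gave as many genes with differing responses as the 914 of the real split. These splits carry the mean response of the lines, so their share says nothing of chance in the difference. The largest, 3730 genes, came from exchanging the treatment labels of 1 line, which turns the difference into the mean response, and so shows the structure of the design. Among the 37 splits that part as many pairs of arrays the highest other was 3730, and among the 63 that part fewer it was 2383. With each gene's mean response taken out of the treated arrays, 1 of the same 100 splits, the real one, gave 914 genes, and the highest other gave 18, a share under 0.05 that argues against chance. For the mean response, 1 of 100 splits reached the real 3730, and the highest other was 914.

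Several explanations of the smaller interferon response in L1236 were weighed. A ceiling or a higher start in L1236 would need treated levels there as high as in L428, and over the list they were lower by a median of -2.65 (95% interval -3.28 to -1.67), with 0.26 between the untreated lines. The weaker response of treated replicate 1 was not the source, since without the arrays numbered 1 the median difference was -2.28 (-2.96 to -1.80) and 33 of 40 members had a smaller response in L1236. Both intervals resample genes as if they were independent, while their estimated correlation was 0.708. They carry no spread between arrays. A larger induction of interferon itself in L428 stays open. Apart from IFNL2, which prompted the test, 0 of 17 interferon genes rose there with a called smaller response in L1236. Of all 18, however, 3 rose in L428 (IFNB1, IFNL1 and IFNL2) and 0 rose in L1236. With IFNL2 the share with a smaller response was 5.56% of 18, against 1.95% of other genes. IFNL2 is the only such member, so no p-value is given. Whether a biological difference between the lines underlies it was not tested and stays open.

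Probe sets without a single gene name lay outside the comparisons of genes and carried a signal of treatment. Of 13522 such probe sets, 351 were called in L428, 148 of them higher, and 644 in L1236, 292 of them higher. No explanation of these was tested.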

How the results depend on the processing

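The settings without all arrays numbered 1, and with the replicate number as a block over both lines, were chosen after the data were seen. No named gene and no gene list reversed its direction past the threshold under any setting. The balance of higher and lower calls did turn. Without the arrays numbered 1, the share of higher genes fell from 71.3% to 49.6% in L428 and from 57.5% to 48.6% in L1236. It fell from 57.7% to 47.9% for the difference and from 55.4% to 49.2% for the mean response. With median centring, lower genes outnumbered higher ones in L1236 and for the mean response. With median centring, cyclic loess, the dimmest genes left out, or trended and robust moderation, each total count of genes stayed within 1.5 times the reported total. Counts of lower genes moved more: with median centring from 1256 to 2066 in L1236 and from 1665 to 2563 for the mean response, without the dimmest genes from 264 to 404 in L428 (from 59 to 121 by at least 2-fold), and with the trended and robust prior from 264 to 171. Testing all probe sets gave 1647 in L428, 4927 in L1236, 1403 for the difference, 6640 for the mean response and 11508 for the untreated lines, since more features were tested. Array weights gave 6561, 9726, 5718, 10251 and 8760 in the same order, but their estimation did not converge. With them camera lost JAK-STAT genes (0.104), Hodgkin Reed-Sternberg cell markers (0.104), MHC class II genes (0.217) and pro-survival genes (0.0568) in L428. For the difference it lost germline genes and T-cell and NK-cell markers (0.0875 each). It gained housekeeping genes in L428 (0.0289), and pro-death (0.0269) and cell-cycle genes (0.00307) in L1236. The block by replicate number within the lines gave 497 for the difference (381 by at least 2-fold), and for the other total counts of genes and lists it changed no count by over 1.5 times. It ended 30 named calls of genes and 3 of lists. The block over both lines moved no total count by over 1.5 times, and ended 5 named calls of genes and those of the lists of pro-survival genes (0.0588) and stromal markers (0.0579) in L428, p53 targets in L1236 (0.0862) and T-cell and NK-cell markers for the difference (0.0620). With only the arrays of L428, 206 genes were called there (152 by at least 2-fold), with fewer arrays to estimate the variance, and fits on only the groups compared ended 39 named calls of genes. Without all arrays numbered 1 the counts were 5717, 6817, 4697 and 7705 for L428, L1236, the difference and the mean response. With 1 array left out in turn they ranged from 368 (without treated L428 replicate 3) to 3532 (without treated L428 replicate 1), from 1506 (without untreated L1236 replicate 3) to 4488 (without treated L1236 replicate 1), from 442 (without untreated L1236 replicate 3) to 2112 (without treated L1236 replicate 1), and from 2322 (without treated L428 replicate 3) to 5442 (without treated L428 replicate 1). Lists called in L428 ranged from 9 (without treated replicate 1) to 13. With an estimated correlation between genes, camera called 0 of 23 lists in L428 and 0 in L1236, with 6 and 8 at an unadjusted p under 0.05, and fry called 6 and 18. Except where a reason is given, the cause was not tested. Low signal limits fold changes, since genes near the lower end of the scale have no measured level to compare with, and 3 arrays per group limit the error.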

Other observations

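Chosen after the results were seen were the gene groups of the next paragraphs, tested in a family of 30 Fisher's exact tests with adjusted p-values, and the tests of an untreated sample labelled as treated and of silent genes. Replication-dependent histone genes, whose mRNAs usually lack poly(A) tails, rose in 17 of 52 members in each line, against 3.24% of other genes in L428 (adjusted p = 1.30e-11) and 8.53% in L1236 (8.33e-06). H2BC11 rose by 4.33 ± 0.34 and 3.08 ± 0.34, H2BC12 by 3.16 ± 0.23 and 1.92 ± 0.23, H4C8 by 5.25 ± 0.78 and 3.95 ± 0.78, while H2AC6 rose by 6.71 ± 0.78 in L428 and had a change of -0.11 ± 0.78 in L1236. The p-values of groups chosen from seen values are not independent tests, and histone genes share sequence, so their probe sets are not independent. Guanylate-binding protein and apolipoprotein L genes rose in 6 of 13 members in each line (46.2%), against 3.29% and 8.57% of other genes (1.37e-05 and 0.00173), with GBP1 at 5.14 ± 0.90 and 3.39 ± 0.90, GBP4 at 3.48 ± 0.60 and 2.91 ± 0.60 and GBP5 at 2.51 ± 0.45 and 1.88 ± 0.45. Of 18 interferon genes, IFNB1, IFNL1 and IFNL2 rose in L428, by 4.89 ± 0.82, 5.15 ± 0.68 and 6.17 ± 0.31, a share of 16.7% against 3.31%. IFNL2 prompted this group and is among them, so no p-value is given. In L1236, 0 of the 18 rose.

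Of 29 S100 and galectin genes, 8 rose in L1236 (27.6% against 8.56% of other genes) and 5 in L428 (17.2% against 3.30%), and 7 had a larger response in L1236 (24.1% against 2.63%). LGALS3 and S100A11, which prompted this group, are among the 8 and the 7, so no p-value is given. Among the called members, S100A6 rose by 5.49 ± 0.19 and S100A16 by 3.61 ± 0.26 in L1236, S100A4 by 2.70 ± 0.48 and LGALS9 by 1.89 ± 0.36 in L428, and S100P in both, by 2.87 ± 0.26 in L428 and 5.37 ± 0.26 in L1236. Of the 29, 0 had a called smaller response in L1236, so no member was shown to respond more in L428. Of 57 ribosomal protein genes, 20 fell in L1236 (35.1% against 6.27%, adjusted p = 1.86e-09), with a median of -0.14 and RPL35A at -0.71 ± 0.06. With cyclic loess 6 fell and 2 rose, and the median was -0.04, so that this depended on the scaling. In L428 the median was -0.02, and 0.05 with cyclic loess.

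Splits of the 6 arrays of a comparison into other groups of 3 number 10, too few for a share under 0.05. In L428 the real split gave 920 genes and the highest other 6, in L1236 2955 and 5, and between the untreated lines 5699 and 1. In each of these 3 cases 1 of 10 splits gave as many genes. Among the splits parting as many pairs of same-numbered arrays the highest others were 3, 5 and 0, and among those parting fewer 6, 1 and 1. For gene lists, 1 of 10 splits gave as many as the real 14 in L428 (highest other 10) and the real 13 in L1236 (highest other 12). The number of called lists thus hardly sets the real split apart in L1236. The other splits still hold unequal numbers of treated and untreated arrays, so they carry part of the treatment response.

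Over genes that changed at least 2-fold in the other line, treated replicate 1 showed a smaller response in both lines. On the mean response of replicates 2 and 3 its slope was 0.521 (95% interval 0.483 to 0.553) in L428 and 0.780 (0.735 to 0.822) in L1236. Replicates 2 and 3, each set against the mean of the other 2, had slopes of 1.07 to 1.25. That mean includes the weaker replicate 1, which raises these slopes, so they are not on the same reference. The intervals resample genes and carry no spread between arrays. An effect added to all arrays numbered 1 would leave the slope near 1, and the larger slope of 0.780 argues against it, as the smaller slope of 0.521 does against an untreated sample labelled as treated. A compressed range of these arrays would shrink the difference between the lines too, and that slope was 1.00 (0.988 to 1.02) over 2491 genes. The cell-cycle list differed in direction, not only in size. Its mean was 11.42 in treated L1236 replicate 1, above 11.10 to 11.30 without treatment, and 10.77 and 10.70 in treated replicates 2 and 3. In L428 it was 11.6, above 11.48 to 11.53 without treatment, and 11.27 and 11.36 in treated replicates 2 and 3. A weaker exposure or another property of the arrays numbered 1 may remain, as may another analogue in treated L428 replicate 1, whose source name reads Aza, and none of these was tested.

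Genes silent in 1 untreated line (below 4 log2) and expressed in the other (8 or more) rose at least 2-fold more often than genes silent in both. The shares were 15.8% (31 of 196) against 1.59% (139 of 8765) in L428 and 43.6% (61 of 140) against 4.37% (383 of 8765) in L1236, differences of 14.2 and 39.2 percentage points. Regression to the mean through the shared untreated arrays was not the source of the rises. The share of such genes at least 2-fold higher, called or not, was 28.6% in L428 and 47.1% in L1236, and 28.4% (of 190) and 45.6% (of 136) when silence and response were read from different untreated arrays, so that 99.5% and 96.7% of that share remained. Genes silent in both lines may include probe sets that detect nothing in any sample, while a signal in the other line requires a working probe set. The shares could differ for this reason alone, which was not tested. That expression in the other line marks silent genes that rise after 5-Aza-dC is thus only a hypothesis, found and tested on the same data. A biological difference between the lines was not tested.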
